A study of Mus musculus with 10 samples.

How the data were processed

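Single-cell RNA-seq libraries of dissociated mouse lung tumours were analysed, 10 libraries in all. The sgControl_RPP group held 3 animals (165, 168 and 1198) and the sgKdm6a_RPP group 6 animals (1117, 1119, 1121, 1270, 1274 and 1314). The sources used here do not expand the abbreviation RPP. The labels describe collection sets that differ in protocol: all 3 control animals and animals 1117, 1119 and 1121 belong to the first, and animals 1270, 1274 and 1314 to the second. Animal 1314 gave 2 libraries, called 1314-1 and 1314-2 here, which were summed to 1 animal because the second set's protocol names 3 animals for its 4 libraries. For shares of cells with a UMI of a gene, the percentages of these 2 libraries were averaged instead, which gave 0.969% for Neurod1.

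The deposited matrices hold raw UMI counts for 32287 features, of which 32285 are Ensembl genes and the others EGFP and Cas9, and they list every barcode rather than called cells. Cell Ranger 6.0.2 with the mm10 genome made these counts, per the submitters' processing notes. No cell annotation of the authors was used here. Gene coordinates came from GENCODE's annotation of the same build, in which 32235 features were matched by Ensembl identifier. Counting can split or drop reads that near-identical genes share, so values of such genes (the H2-Q genes, immunoglobulin variable genes, and ribosomal protein genes with processed copies) are uncertain.

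Filters, lists, tests and the rule for naming genes were chosen before the data were examined, except where the closing section says otherwise. A barcode was kept with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs, up to 10000 barcodes per library. Doublets were scored per library with Scrublet in scanpy, and the highest-scoring barcodes were removed at a rate of 0.8% per 1000 cells. This removed 1767 barcodes, from 3 to 663 per library, and left 36243 cells. Counts were normalised to 10000 per cell and log-transformed. Clustering used 3000 variable genes, 30 principal components, 15 neighbours and Leiden at resolution 1, without integration across libraries. EGFP, Cas9, Kdm6a, sex-linked, mitochondrial and haemoglobin genes were left out of the variable genes.

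The 28 clusters were named from fixed marker lists. A cluster's own genes had to include at least 3 markers, each found in at least 10% of its cells and over 2-fold above the other clusters. Related clusters were read together at a branch distance of 0.25, and leading genes were taken among the top 10 found in at least 25% of cells. This gave 9 classes, and 20 clusters were SCLC tumour-like. Tumour-like cluster 9 held 1103 cells with a low median of 1602 UMIs, and it was kept in the class, with its removal tried as an alternative.

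UMIs were summed per animal within a class, so that the animal was the replicate. Genes that passed filterByExpr were fitted with edgeR's quasi-likelihood test (TMM scaling, robust) with Benjamini-Hochberg adjustment at 0.05, as sgKdm6a minus control. CPM values are TMM-scaled by edgeR unless called plain CPM. Classes were tested when each group had at least 3 animals with at least 30 cells. The collection set was not in the design because the second set holds sgKdm6a animals alone, so values within the first set are given beside it. Gene lists with at least 5 tested members, 34 in number, were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Shares of cells with a UMI of a gene were compared after thinning each cell to 2000 UMIs, with a two-sided exact permutation test over animals. With 3 animals against 6 that test has 84 splits and a smallest p of 0.024, and with 3 against 3 it has 10 splits and a smallest p of 0.1. Intervals for single libraries are exact (Clopper-Pearson) 95% binomial intervals, a count of 0 is given the limit of 3 counts, and all of these cover counting error only.

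The text names Kdm6a, Neurod1, Pou2f3 and Yap1 by rule. It also names up to 10 genes per direction past the threshold with a mean of at least 20 CPM in the higher group and no overlap between groups, up to 4 members per list by smallest p, and up to 5 genes per direction in other classes. Where too few passed, the next genes by p are given as values only. Some planned results are not reported here.

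The steps were tested on simulated counts with 200 changed genes, 50 at each size. For the tumour-like cells, with 15181 genes tested, edgeR recovered 6% of genes changed by 1 log2 unit, 46% at 2, 90% at 4 and 90% at 6, with 2 false calls among 118, and DESeq2 recovered 18%, 78%, 96% and 96%, with 52 false calls among 197. For the first set alone edgeR recovered 0%, 66%, 84% and 88%, with 9 false calls among 128. For the macrophage-like cells it recovered 36%, 88%, 100% and 94%, with 6 false calls among 165. For lists, camera found 5 of 5 raised and 0 of 5 unchanged ones. The simulated genes were drawn independently, and every gene of a raised list moved by 1 log2 unit. This run therefore does not show how often camera calls lists falsely when genes are correlated.

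Alternatives covered DESeq2, other scaling, no expression filter, other cell filters, no doublet removal, no cell typing, cells picked by marker UMIs, thinned or equal-sized animals, the collection set (first set alone, or as a covariate), the libraries of animal 1314, and each animal left out in turn. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Sequence variants and edits at the Kdm6a locus were not analysed here, because the counts hold no reads.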

Results

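Lung tumours from mice that received a control guide (sgControl_RPP) or a guide against Kdm6a (sgKdm6a_RPP) were dissociated and profiled by droplet 5' single-cell RNA-seq, with tumours from 3 control animals and 6 sgKdm6a animals. The animals carried a Cre-dependent Cas9 knock-in, and the labels call the cells tumour cells. The deposited matrices of control animals 165, 168 and 1198 held 38051884, 25000308 and 24994846 UMIs. Those of sgKdm6a animals 1117, 1119, 1121, 1270 and 1274 held 25632383, 54114641, 21630284, 14248173 and 29696764 UMIs, and libraries 1314-1 and 1314-2 held 38592310 and 47525476. After filtering, 2558, 3205 and 1398 control cells remained, against 1507, 7005, 1886, 593, 3320, 6332 and 8439 sgKdm6a cells in the same order. SCLC tumour-like cells made up 31933 of the 36243 cells, 5861 in control and 26072 in sgKdm6a animals. Their median depth ran from 2297 UMIs per cell in library 1314-2 to 11324 in animal 1117, and their summed UMIs per animal from 2585259 in animal 1270 to 46622436 in animal 1314. All control animals came from the first collection set, so the second set (animals 1270, 1274 and 1314) has no control of its own.

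Kdm6a, the targeted gene, encodes a histone H3K27 demethylase and lies on the X chromosome (ENSMUSG00000037369, mm10 positions 18162575 to 18279936). Its RNA in tumour-like cells overlapped between the groups. Kdm6a was at 41.0, 44.2 and 52.6 CPM in control animals 165, 168 and 1198, and at 18.2, 55.8, 21.2, 87.7, 35.7 and 53.1 CPM in sgKdm6a animals 1117, 1119, 1121, 1270, 1274 and 1314. The means were 45.9 ± 5.99 CPM (SD) in 3 control animals and 45.3 ± 26.0 in 6 sgKdm6a animals, a log2 change of -0.03 ± 0.443 (SE, edgeR adjusted p = 0.988), and of -0.54 within the first set. Sex appeared mixed in both groups: control animal 1198 and sgKdm6a animal 1270 had the RNA pattern of females, with Xist at 602.6 and 610.4 plain CPM in tumour-like cells against at most 0.51 in the other 7 animals, and they had the highest Kdm6a value of their group. Tumour-like cells of animal 1119 had raised RNA along the whole X chromosome (median 0.68, 86.4% of genes above the median animal). The Kdm6a change was -0.214 in the 7 animals with Y-linked RNA, a fit added after seeing the data, and -0.317 without animal 1270, and it did not pass in either fit (edgeR adjusted p = 0.926 and 0.801). A small edit made by Cas9 need not lower the RNA, so this measure does not check which cells carried an edit. The Cas9 and EGFP transgenes were close between groups, at log2 changes of 0.06 and -0.14.

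**Figure D1:**
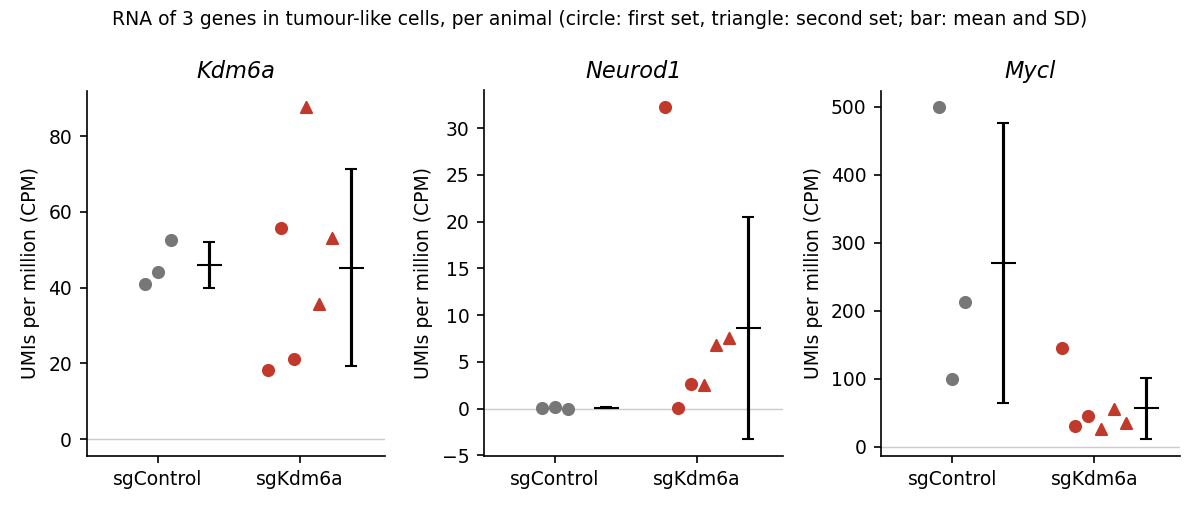
Each panel plots TMM-scaled CPM in SCLC tumour-like cells (y axis) of each animal for Kdm6a, Neurod1 or Mycl, with grey for sgControl_RPP and red for sgKdm6a_RPP, circles for the first and triangles for the second collection set, and bars for the mean ± SD. Kdm6a overlapped between groups, Neurod1 reached 32.2 CPM in animal 1117, and Mycl reached 499.8 CPM in control animal 165.

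The first comparison asked whether tumour-like cells of sgKdm6a animals differed in Neurod1, Pou2f3 and Yap1, which name SCLC subtypes, since the series concerns subtype plasticity. Neurod1, a neuronal transcription factor, was nearly absent from controls and present in most sgKdm6a animals. Neurod1 gave 2, 2 and 0 UMIs in tumour-like cells of control animals 165, 168 and 1198, and 504, 2, 41, 7 and 91 in sgKdm6a animals 1117, 1119, 1121, 1270 and 1274. Library 1314-1 had 388 Neurod1 UMIs and library 1314-2, from the same animal, had 0, and whether these libraries hold the same tumour is not given in the sources used here. Yap1 was low in both groups, and Pou2f3, which names the tuft-cell-like subtype, was below the expression filter and was not tested.

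Neurod1 (ENSMUSG00000034701, chromosome 2, 79452521 to 79456751) was at 0.0696 ± 0.0642 CPM in 3 control animals and 8.63 ± 11.9 in 6 sgKdm6a animals. Its fitted log2 change of 6.76 ± 1.74 (SE) rested on 4 control UMIs, and it did not pass with edgeR (adjusted p = 0.527) but did with DESeq2 (adjusted p = 0.000148). Within the first set alone Neurod1 was below the expression filter. Yap1 was at 1.25 ± 0.403 and 1.94 ± 2.52 CPM (edgeR adjusted p = 0.862), and its sign turned within the first set, at -1.50.

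Cells with Neurod1 RNA were a small part of the tumour-like cells in most sgKdm6a animals and nearly missing in control animals. After thinning to 2000 UMIs, 35 of 1010 tumour-like cells of animal 1117 carried a Neurod1 UMI, 24 of 2136 in animal 1274, 5 of 1418 in animal 1121 and 2 of 270 in animal 1270, as did 85 of 4388 in library 1314-1. No such cell was seen among 4707 cells of animal 1119 or 4897 cells of library 1314-2, which allows shares of cells with a captured UMI of up to 0.064% and 0.061%. In controls, 1 of 2304 cells of animal 168 carried it, and 0 of 1886 and 0 of 943 cells of animals 165 and 1198, which allows up to 0.159% and 0.318%.

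The mean Neurod1 share was 0.0145% ± 0.0251 (SD) in 3 control animals and 1.11% ± 1.23 in 6 sgKdm6a animals, a difference of 1.09 percentage points (two-sided exact permutation p = 0.0952). Animal 1117 had the highest share, 3.46% (exact 95% interval 2.42 to 4.79), and without this animal the difference was 0.623 (exact p = 0.143). Without animal 1119, whose share was 0%, the difference was 1.32 (exact p = 0.0357). Within the first set it was 1.26 (exact p = 0.40, where 0.1 is the smallest possible). Without thinning the shares were 0.0454% ± 0.049 and 4.23% ± 6.95 (exact p = 0.0714), with 220 of 1201 cells (18.3%) in animal 1117. Thinning left out 728 control cells (12.4%) and 7246 sgKdm6a cells (27.8%), all with fewer UMIs. Macrophage-like cells, which should lack Neurod1, carried it in 2 of 1517 cells unthinned and in 1 of 796 sgKdm6a cells after thinning, at median depths of 1730 to 8111.5 UMIs per library against 2297 to 11324 in tumour-like cells.

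**Figure D2:**
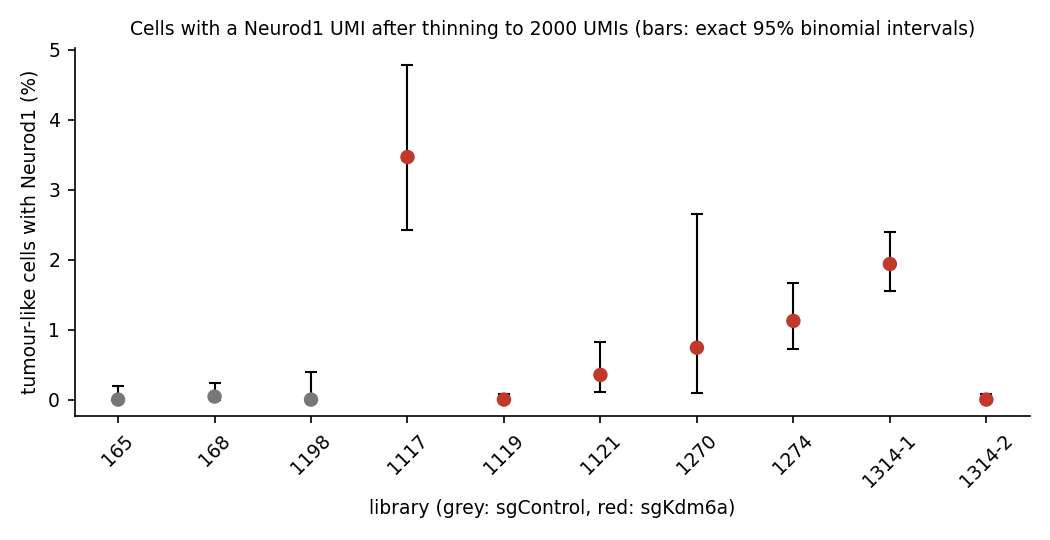
The y axis gives the percentage of SCLC tumour-like cells with a Neurod1 UMI per library after thinning to 2000 UMIs, grey for sgControl_RPP and red for sgKdm6a_RPP, with exact 95% binomial intervals as bars. Animal 1117 stood highest at 3.46%, and libraries 1119 and 1314-2 were at 0%.

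The second comparison asked which genes differed between control and sgKdm6a tumour-like cells. No gene passed, and the genes named here are those of smallest p whose values did not overlap between the groups, given as values only. Higher in every sgKdm6a animal were Cacnb4, a calcium channel subunit, Chrm2, a muscarinic receptor, Chn1, a signalling protein of axons, Negr1, a neuronal adhesion protein, Slc4a8, a bicarbonate transporter, Stx16, a vesicle fusion protein, Zeb2, a repressor of epithelial genes, Acap3, Abca1 and Gm26782. Lower in every sgKdm6a animal were the metallothioneins Mt1 and Mt2, the ribosomal protein genes Rpl13, Rpl15 and Rpl22l1, the stress-response gene Gadd45a, the chromosome 4 neighbours Cap1 and Trit1, and Nme9 and Ciao2b.

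Of 15494 genes tested with edgeR, 0 were higher and 0 lower at an adjusted p of 0.05, with a smallest adjusted p of 0.425, while 1334 had an unadjusted p under 0.05 (857 higher, 477 lower) and DESeq2 called 142 of 16242 (100 higher, 42 lower). The groups did not overlap in 322 genes that were higher and 311 that were lower in sgKdm6a animals, 2.08% and 2.01% of those tested, where chance gives 1.19% each. Within the first set edgeR called 0 genes, with 886 under an unadjusted p of 0.05. Leaving out animal 168 gave 2 lower genes, Trit1 (-3.17, edgeR adjusted p = 0.0056) and Cap1 (-2.60, edgeR adjusted p = 0.0243), and leaving out animal 1117 gave 1, Fgf21 (edgeR adjusted p = 0.0232), a gene chosen after its values were seen. The count under an unadjusted p of 0.05 was 678 without animal 165, 756 without 168, 857 without 1198 and 2472 without 1117. Clusters 2, 3 and 4 held most of the class in control animals, but cluster 2 also held 672 of the 1201 tumour-like cells of sgKdm6a animal 1117. Clusters 1, 11, 14, 15, 20 and 25 held most of the class in sgKdm6a animals, with cells pooled over animals. Of these, clusters 1, 11 and 15 came mainly from library 1314-2 (64.5%, 62.0% and 55.3%) and cluster 14 from 1314-1 (67.8%). Cluster 20 came mainly from animal 1274 (96.1%), and clusters 22 to 26 came almost wholly from animal 1119. These clusters therefore follow single animals and do not show a difference between the groups.

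Among the higher genes, Slc4a8 (chromosome 15, 100761747 to 100823968) was at 13.6 ± 1.36 CPM (SD) in 3 control animals and 33.6 ± 7.69 in 6 sgKdm6a animals, a log2 difference of 1.31 ± 0.265 (SE). Zeb2 was at 4.8 ± 3.31 against 46.0 ± 35.3 CPM (3.26 ± 0.783), Chn1 at 3.89 against 40.7 (3.39), Negr1 at 1.67 against 43.2 (4.73), Chrm2 at 4.25 against 29.5 (2.81) and Cacnb4 at 3.65 against 20.9 (2.50). Stx16 was at 11.6 against 39.8 CPM (1.77), Acap3 at 12.4 against 32.9 (1.39), Gm26782 at 11.4 against 31.1 (1.45) and Abca1 at 5.31 against 20.8 (1.97). None passed with edgeR (adjusted p = 0.425 for 7 of the 10 and 0.453 for Zeb2, Negr1 and Abca1), and DESeq2 gave adjusted p from 0.000108 for Negr1 to 0.00612 for Abca1. Within the first set all 10 kept their sign, from 1.15 for Acap3 to 5.15 for Negr1.

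Among the lower genes, Gadd45a was at 82.6 ± 10.2 CPM in control and 35.4 ± 7.48 in sgKdm6a animals, a log2 difference of -1.22 ± 0.232 (SE). Rpl13 was at 3281 against 1403 CPM (-1.23), Rpl15 at 2063 against 843 (-1.29), Rpl22l1 at 571 against 170 (-1.75), Mt1 at 2335 against 690.4 (-1.76), Mt2 at 597 against 227 (-1.40), Nme9 at 34.6 against 6.18 (-2.46) and Ciao2b at 136 against 62.5 (-1.12). Trit1 (chromosome 4, 123016597 to 123054949) was at 118 ± 79.1 against 17.7 ± 3.90 CPM (-2.74 ± 0.408) and Cap1 (122859047 to 122886056) at 367 ± 205 against 79.2 ± 19.0 (-2.21 ± 0.359). Both lie beside Mycl, a MYC-family proto-oncogene, and their control means were carried by animals 165 and 1198, where Trit1 was at 128 and 191 CPM against 34.1 in animal 168. The edgeR adjusted p was 0.425 for all 10, and the DESeq2 adjusted p ran from 2.83e-05 for Trit1 to 0.0342 for Ciao2b. Ribosomal protein genes have many processed copies, and Mt1 and Mt2 are similar in sequence, so their levels are uncertain where reads could be split.

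The third comparison asked whether fixed sets of genes moved together in tumour-like cells. The machinery that presents peptides on MHC class I leaned higher in sgKdm6a animals, though the call of this list ended with an estimated correlation (camera adjusted p = 0.812) and with fry (0.762): B2m, its light chain, the peptide transporter subunit Tap1, and the class I genes H2-Q4 and H2-Q7 were higher in all 6 animals than in any control. Genes of axon guidance and of the NEUROD1 programme, among them Stmn2, Nefm, Nrp2, Cntn2, Chrna5 and Myt1, and interferon-response genes such as Igtp, Xaf1 and Oasl2 also leaned higher. Immediate-early and heat-shock genes (Dnajb1, Hspa8), glycolysis genes (Pgk1, Gapdh, Pgam1, with Bnip3l), cell-cycle genes (Gins2 and Tipin of S phase, Cdca8 and Ccnb2 of mitosis) and MYC and ribosome-biogenesis genes (Mycl, Npm1, Srm) leaned lower.

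Of 34 lists tested with limma's camera at a preset correlation, 9 passed an adjusted p of 0.05, 4 higher and 5 lower. None held when the correlation among genes was estimated from the samples, where each of the 9 had an adjusted p = 0.812 with an estimated correlation, and fry, which asks whether a list's genes move on balance in 1 direction, called 0 (limma adjusted p = 0.762 for each). The MHC class I list rose (camera adjusted p = 0.000552, median log2 change 0.63, 17 of 22 members higher), and 4 genes were higher adjusted over the list alone, against 0 over all genes. B2m was at 136 against 458 CPM (1.75 ± 0.47, SE), Tap1 at 19.6 against 58.8 (1.59), H2-Q7 at 33.7 against 194 (2.53) and H2-Q4 at 68.0 against 182 (1.42), with H2-Q7 and H2-Q4 uncertain as near-identical genes. This list also passed within the first set (limma adjusted p = 0.000541) and in all 9 runs that left out 1 animal.

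**Figure D3:**
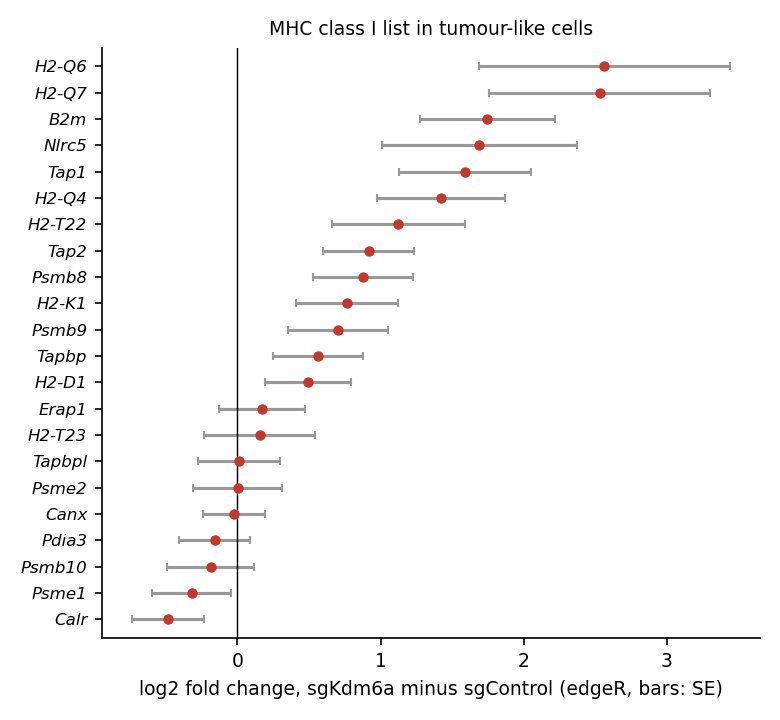
Points give the log2 change (x axis, sgKdm6a_RPP minus sgControl_RPP, edgeR, 3 against 6 animals) of the 22 tested genes of the MHC class I list in SCLC tumour-like cells, with bars for ± SE. Of these genes 17 lay above 0, with B2m at 1.75 and H2-Q7 at 2.53.

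The other 3 higher lists were weaker by camera. Axon guidance had an adjusted p = 0.0238 (30 of 36 members higher, median 0.55), the NEUROD1-associated list 0.0399 (16 of 20, median 0.62) and the interferon list 0.0399 (23 of 26, median 1.04). Within the first set the limma adjusted p was 0.000541, 0.00405 and 0.154. Stmn2 was at 1.39 against 73.3 CPM, Nefm at 5.46 against 53.7, Nrp2 at 8.98 against 27.6, Cntn2 at 0.65 against 3.79, Chrna5 at 1.08 against 4.55 and Myt1 at 20.7 against 34.1. Of the interferon genes Iigp1 was at 0.0421 against 7.03 CPM, Igtp at 4.56 against 17.3, Xaf1 at 3.63 against 9.63 and Oasl2 at 4.13 against 18.4. Animal 1274 carried the interferon means, with Iigp1 at 36.7 CPM (other sgKdm6a animals 0.128 to 3.64), Igtp at 52.3, Xaf1 at 24.7 and Oasl2 at 58.5, as it did for Nefm (192), and animal 1117 had the highest Stmn2 (235). Adjusted over the list alone, 1 NEUROD1-associated gene passed (Neurod1, edgeR adjusted p = 0.0499) and 0 in the axon and interferon lists.

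Of the lower lists, the immediate-early list had a camera adjusted p = 0.0179 (19 of 26 members lower, median -0.48), S phase 0.0238 (24 of 31, -0.21), hypoxia and glycolysis 0.0321 (16 of 23, -0.23), G2 and M phase 0.0355 (23 of 31, -0.20) and MYC with ribosome biogenesis 0.0355 (20 of 25, -0.29). Within the first set the limma adjusted p was 0.000671, 0.896, 0.000671, 0.0454 and 0.438, and the S phase list pointed up there. Adjusted over the list alone, 0 genes passed in each of these 5 lists. Hspa8 was at 2957 against 1584 CPM (-0.90) and Dnajb1 at 313 against 170.1 (-0.88), while Ier3 (0.82) and Hspa1a (2.21) of the same list were higher. Mycl was at 270.5 ± 206 against 56.3 ± 45.1 CPM (-2.26, edgeR adjusted p = 0.527, DESeq2 0.0377), with control values of 499.8, 99.0 and 212.8. Npm1 was at 1048 against 602 CPM, Srm at 267 against 106 and Mga, a MYC antagonist, at 73.3 against 122. Pgk1 was at 697 against 334 CPM, Gapdh at 1437 against 664, Pgam1 at 644 against 336 and Bnip3l at 426 against 242. Gins2 was at 72.2 against 35.1 CPM, Tipin at 199 against 129, Rfc2 at 148 against 112, Dscc1 at 22.9 against 15.9, Cdca8 at 316 against 177, Ccnb2 at 133 against 87.2, Ndc80 at 109 against 80.4 and Birc5 at 194 against 141.

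Apart from MHC class I, each call ended in at least 2 of the 9 runs that left out 1 animal, by camera's adjusted p in limma. The NEUROD1-associated list was at 0.301 without animal 165, 0.102 without 168, 0.175 without 1117, 0.148 without 1119, 0.0517 without 1121 and 0.0715 without 1270. Axon guidance was at 0.0537 without 165, 0.0504 without 168, 0.0593 without 1117 and 0.193 without 1119. The interferon list was at 0.237 without 165, 0.120 without 1117, 0.0995 without 1121 and 0.325 without 1274. S phase was at 0.0509 without 165, 0.0719 without 1270 and 0.0600 without 1274, and G2 and M phase at 0.881 without 1198, 0.401 without 1117 and 0.0600 without 1274. The MYC list was at 0.0785 without 1198, 0.0926 without 165, 0.0730 without 1119, 0.0600 without 1274 and 0.0906 without 1314. Hypoxia and glycolysis was at 0.164 without 1198, 0.130 without 165, 0.273 without 1119 and 0.0517 without 1121, and the immediate-early list at 0.0785 without 1198 and 0.0696 without 1119. The number of lists called was 3 without animal 165, 6 without 1198 and 5 without either 1117 or 1119.

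The lists of secretory granule, epithelial, homeobox and chromatin genes did not pass over all animals. The secretory granule list, with Stx1a (3.65), Kif1a (1.24), Chgb (1.34) and Pcsk2 (1.16), missed the threshold at a camera adjusted p = 0.0524 (24 of 32 members higher) and passed within the first set (0.000684), and without animal 1198 (0.0220), 1270 (0.0239), 1274 (0.0293) or 1314 (0.0409). Epithelial adhesion and keratins (Cldn4 -1.52, Krt8 -0.64, Krt19 1.71) was at 0.112, lower, and passed within the first set (0.000684) and without animal 1121 (0.0325), 1274 (0.0393) or 1314 (0.0132). Without animal 1119 the epithelial list pointed up (0.910), and Cldn4 was at 8.71 and Krt8 at 191 CPM in that animal. The homeobox list (Hoxb8 1.23, Hoxb3 0.83) was at 0.451, higher, and at 0.000684 within the first set. Without animal 1119 it pointed down (0.741), and Hoxb8 was at 456 and Hoxb3 at 104 CPM in that animal. Chromatin regulators of the H3K27 and COMPASS-like kind, which work with or against KDM6A, were at 0.236, with Kmt2c (1.07), Kmt2d (1.67) and Ep300 (0.77) leaning up and Dpy30 (-0.71) down. This list was at 0.923 within the first set and these genes at 0.504, 0.121, 0.194 and -0.411, and Kmt2d was at 14.9 to 20.7 CPM in the first-set sgKdm6a animals and at 71.2 to 109 in the second set, against 13.2 to 18.0 in controls.

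The remaining lists did not pass with camera. Tuft and POU2F3-associated genes (Dclk1 1.57) had an adjusted p of 0.119, MHC class II (Cd74 1.03) 0.199, mesenchymal transition (Zeb2, Vim 1.54, Lox 3.18) 0.226, the mitochondrially encoded genes 0.330, p53 targets (Gadd45a, Zmat3 0.96) 0.450, YAP1 and Notch-driven non-neuroendocrine genes (Ccn1 1.80, Wwtr1 1.75) 0.592, sex-linked genes 0.696, Notch ligands and targets (Maml2 1.54, Dlk1 5.19) 0.876 and neuropeptides (Npy 4.39, Iapp 1.74) 0.876. Single animals carried several of these values, with Dlk1 at 138 CPM in animal 1119, and Lox at 44.8, Ccn1 at 37.1 and Npy at 17.8 CPM in animal 1270. Adjusted over the list alone, Zeb2 (0.0328, edgeR) passed upward in the mesenchymal list and Gadd45a (0.00512, edgeR) downward in the p53 list. The mitochondrially encoded list passed downward within the first set (0.0405), against its pooled median of 0.30. Cell type marker lists, read as a sign of RNA from other cells, were at 0.0524 for macrophage, 0.228 for airway, 0.330 for fibroblast, 0.384 for B cell, 0.439 for T or NK cell, 0.658 for endothelial, 0.696 for erythroid, 0.876 for alveolar, SCLC tumour and dendritic and 0.945 for neutrophil markers. The macrophage list passed without animal 168 (0.0387), 1119 (0.0377) or 1314 (0.0409), and the erythroid list passed upward within the first set (0.0312). Medians and the test differed in sign for erythroid (2.01), alveolar (0.33) and neuropeptide (0.66) genes, which camera placed lower, and sex-linked genes had a median of 0.17 and a mean of -0.10.

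The fourth comparison measured how far sgKdm6a tumours of the second collection set differed from those of the first. edgeR called 0 genes, with 3341 under an unadjusted p of 0.05, and DESeq2 called 1478 (684 higher and 794 lower in the second set). Without animal 1119 edgeR called 506, and the count was 2 without animal 1117 and 1 without either 1121 or 168. Whole tumour-like profiles of single libraries resembled each other more among controls (correlation across genes 0.932 to 0.95) than among sgKdm6a libraries (0.804 to 0.913, median 0.872), which were no closer to each other than to controls (0.836 to 0.933, median 0.897), with 0.975 for the pair of libraries from animal 1314, where genes are not independent replicates.

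The fifth comparison covered cell types around the tumour cells. Macrophage-like, T or NK cell-like, B or plasma cell-like, endothelial, fibroblast, lung epithelial, mesothelial and neutrophil-like cells were found, and no class passed a test of its share. Tumour-like cells were 82.8% ± 4.06 (SD) of cells in 3 control animals and 80.0% ± 16 in 6 sgKdm6a animals (two-sided exact permutation p = 0.952), macrophage-like cells 6.88% ± 1.6 and 7.52% ± 6.87 (exact p = 0.881), and T or NK cell-like cells 3.02% ± 1.23 and 1.65% ± 0.888 (exact p = 0.119). B or plasma cell-like cells were 3.04% and 2.35%, endothelial 2.37% and 3.01%, fibroblast or mural 1.19% and 2.97%, lung epithelial 0.38% and 1.17%, mesothelial 0.113% and 0.853%, and neutrophil-like 0.212% and 0.433%. The smallest adjusted p over the 9 classes was 0.918 by the exact permutation test. Its smallest possible p was 0.024 before adjustment over 9 classes, so a single class could hardly pass, and this result does not show equal shares. The first-set differences for tumour-like, macrophage-like and T or NK cells were 0.77, -1.31 and -1.43 percentage points. Without animal 1270 the tumour-like difference turned from -2.76 to 3.43 and the macrophage-like difference was -2.03, and the sgKdm6a means of fibroblast or mural, lung epithelial and mesothelial cells were 1.54%, 0.43% and 0.181%.

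In macrophage-like cells, in which the Cre-dependent Cas9 is not meant to be active, Jun, an immediate-early factor, Arid5a, an RNA-binding regulator of inflammation, St3gal5, Bmyc and the interferon-signalling gene Stat2 were higher in every sgKdm6a animal. Vamp4, Sept9, Phgdh, a serine-synthesis enzyme, Fabp1 and Inf2 were lower in every one. None of the 8589 genes passed with edgeR (0 higher, 0 lower, smallest adjusted p = 0.244, 643 at an unadjusted p under 0.05), and DESeq2 called 20 (4 higher, 16 lower). Arid5a was at 24.8 against 70.6 CPM (1.47 ± 0.269, SE), Jun at 416 against 776 (0.90), St3gal5 at 8.87 against 26.8 (1.70), Bmyc at 16.1 against 41.2 (1.23) and Stat2 at 15.95 against 37.3 (1.12). Vamp4 was at 122 against 60.1 CPM (-1.03 ± 0.168), Sept9 at 136 against 69.7, Phgdh at 25.1 against 3.02, Fabp1 at 21.6 against 1.57 and Inf2 at 39.1 against 16.2. Without animal 1198 edgeR called 1 gene (Ramp1) and without animal 1274 it called 2 (Sdc1 and Ear1), all lower and chosen after their values were seen. Camera called 6 lists: interferon higher (adjusted p = 0.00492), immediate-early higher (0.0126), SCLC tumour markers higher (0.0294, median 1.66), H3K27 regulators higher (0.0294), secretory granule higher (0.0310) and S phase lower (0.0310). Each had an adjusted p = 0.739 with an estimated correlation, and the MHC class I list was at 0.451. The SCLC tumour and secretory granule lists hold genes of the tumour cells. Their rise may therefore be tumour RNA carried into macrophage-like barcodes, which was not tested, and it is not read as a change in macrophages.

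B or plasma cell-like cells of 3 control animals and 4 sgKdm6a animals (1117, 1119, 1274 and 1314) had lower levels of Igkv2-109, an immunoglobulin light chain variable gene, and values of Ms4a1, a B-cell surface protein, were lower in all 4. Igkv2-109 fell by 3.21 on the log2 scale (± 0.48 SE, 197 against 17.7 CPM, edgeR adjusted p = 0.0468), as the only gene of 3004 that passed with edgeR (230 at an unadjusted p under 0.05), and DESeq2 called 11. Reads of similar variable genes such as Igkv1-110 could be split, so this value is uncertain. Ms4a1 was at 929 against 478 CPM (edgeR adjusted p = 0.202) and Zfp36l1 at 922 against 484, while Atp2a2 (1.58), BC005561 (1.38), Tmem176b (3.25), Tulp4 (1.85) and Scd2 (1.86) leaned higher. The count was 0 without animal 165, 168, 1119 or 1274, 49 without animal 1117, and 1 without animal 1198, where the gene was Igkv6-32, chosen after its values were seen. MHC class II genes (camera adjusted p = 0.000266, median -0.30) and B-cell markers (0.00576, median -0.38) were lower, each at an adjusted p = 0.373 with an estimated correlation. T or NK, endothelial, fibroblast, lung epithelial, neutrophil and mesothelial cells had too few control animals with 30 cells for a test of genes.

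**Figure D4:**
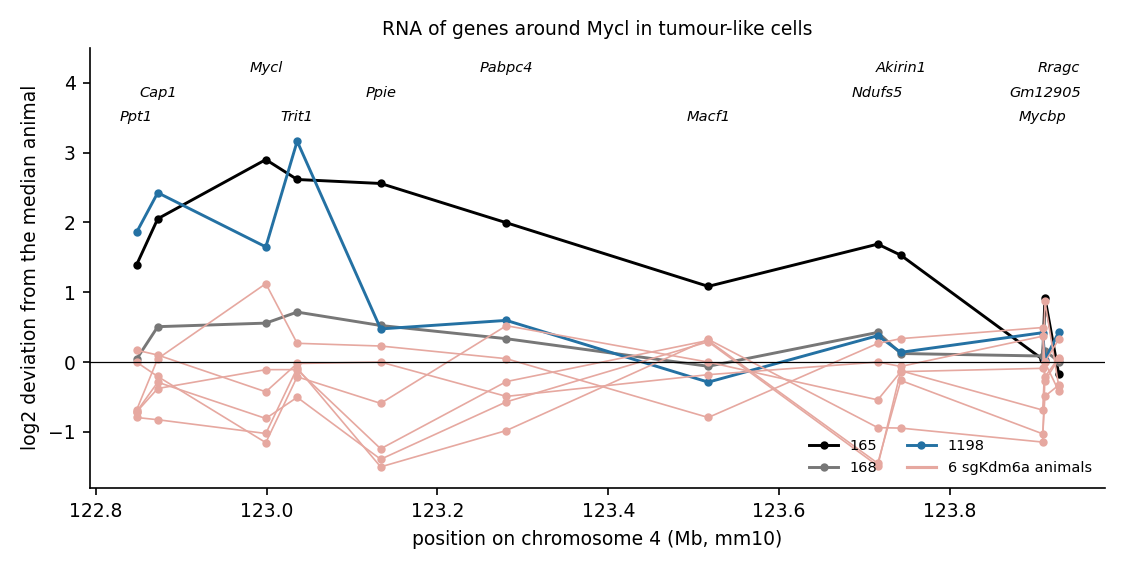
The y axis gives the log2 deviation of each gene from the median animal in SCLC tumour-like cells, along chromosome 4 (x axis, position), with control animal 165 in black, 1198 in blue, 168 in grey and the 6 sgKdm6a animals in pale red. Medians over Ppt1, Cap1, Mycl, Trit1 and Ppie were 2.56 in animal 165 and 1.86 in animal 1198, against 0.52 in animal 168 and -0.83 to 0.23 in sgKdm6a animals.

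**Figure D5:**
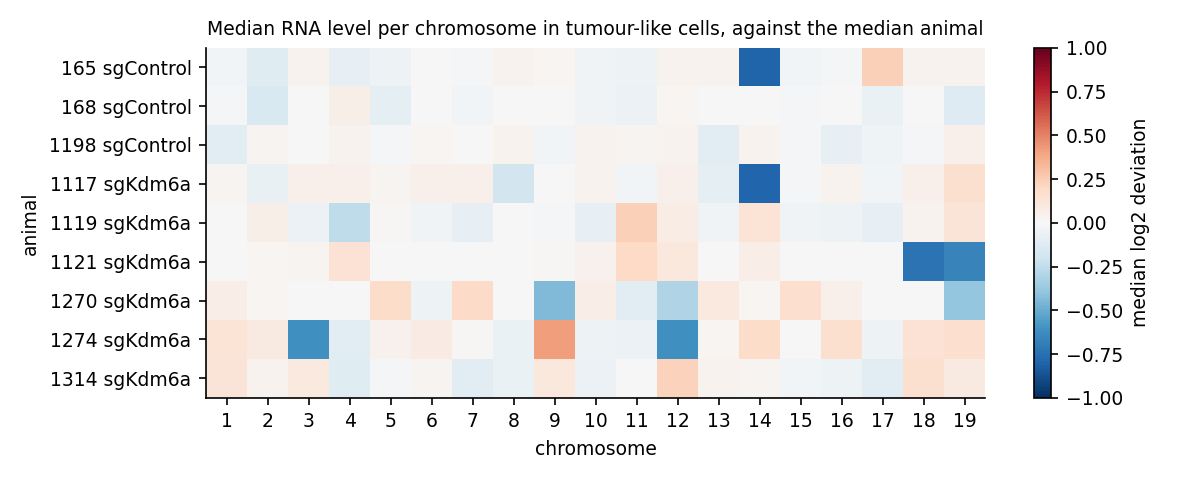
The heat map shows, for chromosomes 1 to 19 and each animal, the median log2 deviation of the chromosome's genes from the median animal in SCLC tumour-like cells. Chromosome 14 was at -0.80 in control animal 165 and -0.79 in sgKdm6a animal 1117.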

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

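The test of swapped barcodes and the test for cells of animal 1117 inside library 1314-1 were planned before their results were seen, while the tests of free RNA, misassigned molecules and genotype were chosen only after the result was seen. Each of 33 measures was checked for an animal far from the other 5 sgKdm6a animals by Dixon's ratio at its 95% critical value, and 9 had one. Chance marks about 1 in 20 groups. The 3 control animals are too few for this check.

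Animal 1117 stood apart in Neurod1. After thinning to 2000 UMIs it had a Neurod1 UMI in 3.46% of tumour-like cells (others 0% to 1.12%). Without thinning, 220 of its 1201 tumour-like cells (18.3%) had one, at a median depth of 11324 UMIs. Its Neurod1 was at 32.2 CPM (others 0.0806 to 7.51). In this animal, without thinning, most Neurod1 cells lay in cluster 2, with 145 of its 672 cells (21.6%), near the share of the whole animal. Cluster 4 had a higher share, 42 of 101 cells (41.6%). In library 1314-1 cluster 0 held the most, 64 of 226 cells (28.3%), against 2.52% in the whole library.

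The tables argue against several technical sources of Neurod1 RNA in sgKdm6a tumour cells. Free RNA would reach macrophage-like cells of the same libraries. These carried Neurod1 in 0.39% (2 of 511), against 4.01% (470 of 11712) of tumour-like cells, 9.8% of that share. Animal 1117 gave 220 of these 470 cells, and 0 of its 88 macrophage-like cells carried it. In library 1314-1 the shares were 1.16% and 2.52%, and in animal 1274 0.495% and 2.54%, on 1 macrophage-like cell each. The free RNA test therefore decides little for animal 1274 and library 1314-1. Molecules misassigned between libraries would mostly come singly, but 41.3% of Neurod1 cells (197 of 477) held at least 2 UMIs. Most of these came from animal 1117 (111 of 220) and library 1314-1 (65 of 154). The other counts were 12 of 72 in animal 1274, 8 of 24 in 1121, 1 of 5 in 1270 and 0 of 2 in 1119. This test is therefore weaker for animal 1274 and decides little for animals 1119 and 1270. Of the 470 Neurod1 cells in the 4 libraries with the most, 0% shared a barcode with a Neurod1 cell of another library, and those of library 1314-1 showed 6.7% of the chromosome 14 shift of animal 1117, which argues against cells of that animal. Whether the guide against Kdm6a is the source stays open, with an exact permutation p of 0.0952 over 3 and 6 animals. Age and the growth of single clones were not separated from it, nor was the collection set in animals 1270, 1274 and 1314. Animals 1117 and 1121 shared the first set with all controls, and had 504 and 41 Neurod1 UMIs against 2, 2 and 0. That argues against the collection set alone as the source in animals 1117 and 1121, while animal 1119 of the same set had 2. A candidate explanation is that Neurod1 is switched on in a part of the cells of some sgKdm6a tumours, a hypothesis found and tested on the same data.

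Animal 1270 stood apart in composition. Tumour-like cells made up 49.1% of its cells (others 79.7% to 95%), macrophage-like cells 20.9% (1.44% to 7.16%), fibroblast or mural cells 10.1% (0.985% to 2.26%), lung epithelial cells 4.89% (0.115% to 0.994%) and mesothelial cells 4.22% (0% to 0.42%). Its tumour-like cells had 6.91 CPM of Yap1 (others 0.256 to 1.84) and 20.7 CPM of Gadd45a (34.9 to 40.8). It also had the fewest cells, 593, and the most barcodes removed for mitochondrial RNA, 432. No explanation was tested for these values.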

How the results depend on the processing

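The removal of the low-UMI cluster, alone or with animal 1270, the fit on animals with Y-linked RNA and the matching of 3 cells per Neurod1 cell were chosen after seeing the data. All other alternatives were planned.

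With DESeq2 in place of edgeR, the counts of genes were 142 in tumour-like cells, 1478 between collection sets, 20 in macrophage-like cells and 11 in B or plasma cell-like cells, and in simulated tumour counts 52 of its 197 calls were false. Of the gene lists, 0 passed with an estimated correlation and 0 with fry, where the cause was not tested. The S phase list turned upward within the first set alone (adjusted p 0.896) and with the collection set as a covariate (0.780). The second set has no control, so both settings compare controls with first-set sgKdm6a animals and are not separate checks. The pooled fall of this list therefore rested on the second-set animals, and why they differed was not tested. With no doublets removed, the Neurod1 difference was 1.10 (exact p = 0.0476); the cause was not tested. The number of cells kept was 27143 at a minimum of 2000 UMIs and 43996 at 500 UMIs and 250 genes, by construction of the filter.

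Leaving out each animal in turn gave 0 to 2 tumour genes, 3 to 11 lists, 0 to 2 macrophage genes, 0 to 49 B-cell genes, 0 to 506 genes between collection sets and 0 to 0 classes that differed in share, where the smallest possible p was 0.071 without a control animal and 0.036 without an sgKdm6a animal, before adjustment over 9 classes, so this 0 shows no stability. The Neurod1 difference ran from 0.623 to 1.32. The extremes came without animals 168 (2 tumour genes), 1274 (2 macrophage genes), 165 (3 lists), 1314 (11 lists), 1117 (49 B-cell genes and the lowest Neurod1 difference) and 1119 (506 genes and the highest).

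edgeR's 0 tumour genes held with other scaling, no expression filter, other cell filters, no cell typing, marker-picked cells, thinned or equal-sized animals, either treatment of the collection set, each treatment of animal 1314 and the 3 added fits, but not without animal 168 (2 genes) or 1117 (1 gene). Unadjusted p fell under 0.05 for 1332 genes without the low-UMI cluster, 1116 without it and animal 1270, and 758 in animals with Y-linked RNA. Of 3024 gene and setting pairs over 110 named genes, 2995 kept their side of the threshold (32 of them changed sign without a call), 29 passed newly (27 with DESeq2) and 0 reversed after a call. The main edgeR fit called 0 tumour genes, so a gene counted as kept whenever it stayed uncalled, and there was no call to reverse. The gene counts therefore do not tell whether the size of each change held across settings. Of 117 list and setting pairs, 62 were the same, 53 were weaker and 2 reversed. No paired analysis was possible because the groups share no replicate numbers. Depth limits the Neurod1 shares to cells with a captured UMI, so the limits of 0.061% to 0.318% where none was seen do not bound the cells that express it.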

Other observations

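The tests of splits and macrophage RNA for the MHC class I list, of a library-wide difference at Mycl and of library-wide shifts of chromosomes were planned before their results were seen. The other tests were chosen only after the result was seen: the collection set for MHC class I, the gain at Mycl, Y-linked depth, the Neurod1-cell tests and the splits for the counts of genes and lists.

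Cells with Neurod1 were set against cells without it in the same library, matched 1 to 1 for depth (220 pairs in animal 1117, 24 in 1121, 72 in 1274 and 154 in library 1314-1). Mitotic genes leaned higher in the Neurod1 cells, and MHC class I and immediate-early genes lower, with medians of 0.64, -0.55 and -0.68 log2 units. These medians cover all list members, with differences averaged over libraries. Over the members that camera tested, they were 0.61, -0.63 and -0.76. Camera's calls of these 3 lists ended at an adjusted p of 0.283 with an estimated correlation. Among further lists, camera called interferon, epithelial and secretory granule genes lower. These calls also ended with an estimated correlation (camera adjusted p = 0.283, 0.475 and 0.336). Egr4, an activity-induced transcription factor chosen after its values were seen, was lower in 4 of 4 libraries (-1.60, edgeR adjusted p = 0.00529), the only one of 9399 genes to pass (Neurod1, which defined the cells, was left out), with 787 at an unadjusted p under 0.05. Calca (edgeR adjusted p = 0.204) did not pass, and Kdm6a was at 0.03. Matching 3 cells to each, tried first, left the depth of animal 1117 unmatched, and the 1 to 1 matching followed it. The 3-cell matching gave medians averaged over libraries of 0.60, -0.50 and -0.70. The gene call changed there: Egr4 missed the threshold (edgeR adjusted p = 0.0514). Mest, also chosen after its values were seen, was the only gene to pass (-1.51, edgeR adjusted p = 0.0243).

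Neurod1 cells may carry a wider NEUROD1 programme, but the NEUROD1-associated list without Neurod1 had a camera p of 0.2706. Its median was 0.128 over the 10 members tested, and 0.111 over all members when differences were averaged over libraries. The axon guidance list had medians of 0.277 and 0.258 in the same order. It passed with camera (adjusted p = 0.00282), but not with an estimated correlation (adjusted p = 0.545). Of 100 other genes found in about as many cells, 0 moved either list as far (at most 0.0607 and 0.188 upward). The values go both ways, so this stays open. Any rarely detected gene could pick cycling cells, but 3 of 100 other genes found in about as many cells moved the G2 and M phase list as far, which argues against that, and for the MHC class I and immediate-early lists 0 of 100 did. In library 1314-1 the Neurod1 cells had a chromosome 19 median of -0.56 against matched cells, with 0.213 as the next largest size among 80 chromosome medians, so a separate clone is a hypothesis found after seeing the data, and it was not tested further.

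The MHC class I list rose in sgKdm6a tumour-like cells, with a -log10 p of 4.79 by camera and an adjusted p = 0.812 with an estimated correlation. Chance cannot be excluded, since 11 of the 84 splits of the 9 animals gave as large a value, up to 10.945. RNA of macrophage-like cells would bring a median of 0.2% of the rise of its members (at most 0.84%), so macrophage RNA does not account for it. The list also passed within the first collection set, with a camera p of 3.493e-05 at the preset correlation. The pooled call at that setting ended when the correlation was estimated, so this p does not rule out the collection set. Sharing of reads among H2-Q genes can alter only those genes, but 17 of the 22 members were higher, most of them outside that family. In plain CPM, B2m was at 125 against 483, H2-K1 at 471 against 918, Tap1 at 18.0 against 62.4 and Psmb8 at 108 against 225. These values argue against such sharing as the source of the rise outside the H2-Q genes. The genotype stays open, and a link of MHC class I to Kdm6a is at most compatible with these values.

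Cap1, Mycl and Trit1 lie in an interval of chromosome 4 from Ppt1 (122836242) to Ppie (123139951), whose RNA was high in control tumours 165 and 1198. The medians over its 5 genes were 2.56 and 1.86, as high as at most 0.03% of 10102 runs of 5 neighbouring genes, but the interval was chosen because its genes were high, so this rank does not support a gain. In macrophage-like cells of the same animals, the interval showed at most 20.3% of the tumour shift, which argues against a germline or library-wide difference. In animal 165 the high RNA reached Akirin1 (1.53), and in animal 1198 it ended after Trit1. Animal 168 was at 0.52, so the lower Mycl, Cap1 and Trit1 of sgKdm6a animals rested largely on a pair of control tumours, and a gain stays open because DNA copies were not measured.

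Whole chromosomes were low in single tumours of both groups. Chromosome 14 was at -0.80 in control animal 165 and -0.79 in sgKdm6a animal 1117, chromosomes 3 and 12 at -0.61 in animal 1274, and chromosomes 18 and 19 at -0.74 and -0.67 in animal 1121, with 80.2% to 93.7% of genes below the median animal. Losses of these chromosomes in the tumour cells may be the source, since macrophage-like cells of the same animals showed at most 24.2% of the shift, against a library-wide difference. Tumour-like cells of animal 1274 had Y-linked RNA at 5.45 plain CPM and its other cells at 96.1, a ratio of 17.64, so low depth of Y-linked genes is unlikely and loss of the Y chromosome is a hypothesis. Animals 1198 and 1270 had 1 and 0 Y-linked UMIs in tumour-like cells, but also 0 and 0 in other cells, with Xist at 433.1 and 614.3 plain CPM there, as in females, so these values do not bear on a loss. The X chromosome was at 0.68 in tumour-like cells of animal 1119 and at 0.024 in its macrophage-like cells.

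Other splits of the same animals were used to ask whether chance can be excluded. Where edgeR called 0 genes in the real split, genes at an unadjusted p under 0.05 were counted. Chance cannot be excluded for tumour genes with edgeR (10 of 84 splits gave as many; real 1334, highest other 4011), for tumour genes with DESeq2 (11 of 84; real 142, highest other 2386), for tumour lists (26 of 84; real 9, highest other 14), for macrophage genes at an unadjusted p under 0.05 (13 of 84; real 643, highest other 1244) or for B-cell genes (7 of 35; real 1, highest other 26). The split that set the second collection set (animals 1270, 1274 and 1314) apart from the rest gave these 4011 genes and 924 past the adjusted threshold, which points to a structure of the samples by collection set, and within the first set edgeR called 0 genes, with 886 at an unadjusted p under 0.05. For the difference between collection sets the splits (1 of 10 as large) are too few for a share under 0.05, with a real value of 3341 genes at an unadjusted p under 0.05 and a highest other of 2029.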
